A study of Mus musculus with 3 samples.

How the data were processed

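Gene expression was measured on 3 Affymetrix arrays, 1 for each of 3 groups of cultured mouse peritoneal macrophages, and each array was hybridised with RNA pooled from 3 samples. Per the labels' protocols, the cells came from male Angptl4-/- mice on a C57Bl/6 background, 3 days after an injection of 4% thioglycollate, a sterile irritant that draws macrophages into the peritoneal cavity. Adherent cells were cultured for 2 days and then exposed for 6 h. RNA was used only if its integrity number exceeded 8, and 100 ng was labelled with biotin in a whole-transcript assay. The deposited values are log2 expression values per probe set, 1 column per array, made with RMA (background correction, normalization between arrays and summary of the probes of a probe set) per the submitters' processing notes. The version of RMA, the chip definition, any filter and the hybridisation dates are not given in the sources used here. The protocol also names the lipase inhibitor Orlistat as a pre-incubation, and no sample with it was analysed here.

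The table held 35556 probe sets. The median deposited log2 value was 4.50 on the PBS array, 4.54 on the intralipid array and 4.54 on the array with intralipid plus ANGPTL4. GEO's platform annotation gave 1 gene symbol to 21789 probe sets, several symbols to 1621 and none to 12146. Only probe sets with 1 symbol were used for genes, which left 19938 genes. For the 999 genes with more than 1 probe set, the one with the highest mean over the 3 arrays was taken. Of these genes, 19856 had their gene identifier in the RefSeq gene table of the mouse, and 0 of those had another symbol there. No genome build was named in the sources used here, so no coordinates are given. Values were used as deposited, with no further normalization. The expression floor was the median of all probe sets with a gene name on the same array, a log2 value of 4.98 for PBS, 4.97 for intralipid and 4.97 for intralipid plus ANGPTL4. A total of 10090 genes reached the floor on at least 1 array.

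With 1 array per group, the spread between cultures could not be estimated, so no test was run and no p-value is given. The number of arrays limits the precision, and all comparisons describe these 3 arrays. Genes were counted where the log2 difference between 2 arrays was at least 1 in size (2-fold) and the higher array reached the floor. Gene lists were described by the median log2 difference of their members past the floor on at least 1 array, and by the percentile of that median among 10000 random lists of the same size matched on mean expression (20 bins). A list is said to stand apart where the percentile lies outside the middle 95%, which about 5% of lists of unrelated genes do by chance. Members of a fixed list may move together, so that share need not hold for them. Many genes had a difference of 0, which narrows the random medians, so small medians can stand apart. Ties count as 0.5 in the percentile, and random members were drawn with replacement within bins. A minimum of 5 members was required. The 20 gene lists covered lipid metabolism, stress, inflammation and activation, energy metabolism, ribosomal proteins and the cell cycle, and 11 further lists held markers of cell types that a peritoneal lavage can hold. Of the 542 symbols in the 20 lists, 59 had no probe set of their own, 15 of them because their probe set carried several symbols.

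The text names, per comparison, the 10 genes with the largest difference in each direction among those past the floor (symbols of set patterns for uncharacterised, non-coding or receptor-repertoire genes left out, which do not cover AW112010), up to 4 members of each list that stood apart, and Angptl4, Lpl, Cd36, Plin2, Cpt1a, Pdk4 and Hilpda whatever their values. A further item of this rule is not reported here. The grouping, lists, thresholds, naming rule and alternatives below, save 1, were fixed before the data were examined. Because 14722 probe sets (41.4%) held 1 identical value on all 3 arrays, the spread of differences over genes is given as a robust SD from the central 68% of genes, a choice made after the values were seen. For the genes 2-fold apart between intralipid and PBS, the remaining share is the log2 difference of intralipid plus ANGPTL4 from PBS divided by that of intralipid from PBS. The overlaps and correlations were set beside 100 simulations that added noise per array, with the robust SD of the pair of arrays that differed least, by expression bin. This noise holds no spread between cultures and is small against 2-fold, so the simulated share says nothing about fall-back and is not given.

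The alternatives were fold thresholds of 1.5 and 3, no floor, a floor at a higher percentile, arrays centred on their medians, cyclic loess and quantile normalization, the mean over all probe sets of a gene, unmatched random lists and the mean of a list in place of its median. Leaving out members identical on all arrays was added after seeing the data. On simulated data for 10090 genes with the noise above, the 2-fold rule for intralipid against PBS called 0% of 50 genes set 1.5-fold apart, 100% of 50 genes set 2.5-fold apart and 0% of 9890 genes left equal. The small noise fixes this outcome, so it checks the counting only and not the error of the rule between cultures. Of 100 random lists of 20 genes, 4% stood apart for intralipid against PBS, 3% for ANGPTL4 against intralipid and 6% for ANGPTL4 against PBS, and 100% did so in each after a shift of 0.3 on the log2 scale. Work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1 for the loess and quantile alternatives.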

Results

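Macrophages lacking Angptl4 were exposed to 1 of 3 conditions, and their transcripts were measured on 1 array per condition. Intralipid is an emulsion of triglyceride droplets, given here at 0.5 mM triglyceride for 6 h. ANGPTL4 is a secreted inhibitor of lipoprotein lipase, the enzyme that releases fatty acids from triglyceride-rich particles. The groups were PBS, intralipid, and intralipid after 1.5 h of pre-incubation with 2.5 µg/mL recombinant mouse ANGPTL4. Because the cells made no ANGPTL4 of their own according to their genotype, the arrays address whether the added protein alters the response of macrophages to a triglyceride load. Each array carried RNA pooled from 3 samples, so differences between arrays have no replicate check, and "higher" and "lower" describe these arrays only. Folds are ratios of the deposited log2 values taken back to the linear scale.

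The deleted gene, Angptl4 (probe set 10450038), had a log2 value of 4.92 on each of the 3 arrays, just below the floor. No wild-type array was analysed here, and whether the probes lie in the deleted part is not known, so this value does not check the genotype. Macrophage markers were high, with a median log2 value of 10.36 with PBS, 10.65 with intralipid and 10.64 with intralipid plus ANGPTL4, and 14 of 14 measured members past the floor. Markers of B cells (9 measured), T and NK cells (11) and mast cells (8) had 0 members past the floor. Only 1 of the 7 erythroid markers was measured, so erythroid cells could not be judged. Dendritic cell markers had 1 (Clec9a), eosinophil markers 1 (Siglecf), mesothelial markers 2 and neutrophil markers 4, too few for a percentile. Clec9a reached the floor on the intralipid array only. Of 8 measured fibroblast markers, 6 passed the floor. Over all 8, the median log2 value was 7.66, 7.52 and 7.56 on the arrays in the same order. These arrays do not tell which cells of a culture a transcript came from. The fibroblast list did not stand apart in any of the 3 comparisons. The macrophage list did not stand apart either.

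The arrays with PBS and with intralipid plus ANGPTL4 resembled each other most. Over all probe sets, Pearson's r was 0.994 for that pair, 0.988 for intralipid with PBS and 0.987 for intralipid plus ANGPTL4 with intralipid. These correlations run across probe sets, which are not independent replicates. The robust SD of the log2 differences over genes was 0.10, 0.20 and 0.23 for the same pairs. Smaller differences, such as those given below for Cd36 and the ribosomal protein genes, lie within this spread.

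The comparison of intralipid with PBS asks how these macrophage cultures responded to the lipid load. As groups, inflammatory genes, ATF4 and CHOP targets and immediate early genes were higher with intralipid, and genes of cholesterol and fatty acid synthesis were lower. Cxcl2 (probe set 10523156), a chemokine that attracts neutrophils, was 64.6-fold higher. Fosb, a subunit of the AP-1 transcription factor, was 24.1-fold higher, Inhba, which encodes an activin subunit, 19.0-fold and Hilpda, a lipid droplet protein that inhibits triglyceride lipase, 17.8-fold. Kcnj2, an inward-rectifier potassium channel, was 23.0-fold lower, and Hmgcs1, an enzyme of the mevalonate pathway, 6.60-fold lower. Among 10049 genes, 252 were at least 2-fold higher and 133 at least 2-fold lower, and 85 differed at least 4-fold in either direction.

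The other genes with the largest differences upward were Lsmem1 (16.9-fold), Osm (16.5-fold), Dusp10 (15.1-fold), Il6 (13.6-fold), Ptgs2 (13.4-fold) and Tnfaip6 (13.0-fold). Osm and Il6 encode cytokines, Dusp10 a phosphatase of stress-activated kinases, and Ptgs2 the inducible cyclooxygenase. On the PBS array, Cxcl2, Fosb, Lsmem1, Il6 and Tnfaip6 lay below the floor, as did Kcnj2 (log2 value of 3.96) on the intralipid array, so their folds and ranks depend on values near background. Against the floor itself, the difference would be 53.1-fold for Cxcl2, 16.6-fold for Fosb, 12.3-fold for Lsmem1, 11.4-fold for Kcnj2, 7.35-fold for Tnfaip6 and 2.40-fold for Il6. Downward, the list went on with Hhex (5.72-fold), Sesn1 (5.00-fold), Idi1 (4.63-fold), Tlr1 (4.54-fold), Chst12 (4.29-fold), Lpcat1 (4.26-fold), Tmem50b (4.20-fold) and Tifab (4.02-fold). Idi1 acts in the mevalonate pathway and Tlr1 encodes a receptor for bacterial lipopeptides.

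Of the 20 gene lists, 6 stood apart as higher with intralipid than with PBS and 4 as lower. Immediate early genes, which are transcribed within minutes of many stimuli, had a median difference of 1.59, with 25 of 27 members higher and 19 at least 2-fold (percentile 100). Dusp1 was 12.6-fold higher, Ier3 11.3-fold and Nr4a1 8.62-fold. Targets of ATF4 and CHOP, transcription factors of the integrated stress response, had a median of 0.88, with 22 of 25 members higher, 0 lower and 12 at least 2-fold higher (percentile 100). Trib3 was 6.32-fold, Ddit3, which encodes CHOP, 5.39-fold, Sesn2 4.68-fold and Ppp1r15a 4.56-fold higher. Endoplasmic reticulum chaperones did not stand apart, with a median of 0.00 and 10 of 25 members identical on both arrays. Inflammatory cytokines and NF-kB targets had a median of 0.86, with 24 of 29 members higher, 2 lower and 13 at least 2-fold higher (percentile 100), led by Cxcl2, Osm, Il6 and Ptgs2.

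Cholesterol synthesis genes, targets of SREBP2, had a median of -0.87, with 19 of 21 members lower and 8 at least 2-fold lower (percentile 0). Besides Hmgcs1 and Idi1, the sterol carrier Stard4 was 3.96-fold and Cyp51, a sterol demethylase, 3.71-fold lower. Fatty acid synthesis genes had a median of -0.42, with 14 of 18 members lower, 0 higher and 3 at least 2-fold lower (percentile 0). Their largest differences were in Mid1ip1 (2.60-fold lower), Scd2 (2.57-fold), Elovl6 (2.12-fold, or 1.55-fold against the floor) and Aacs (1.76-fold).

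The remaining lists that stood apart did so by small medians. The alternative activation list had a median of 0.12 with 9 of 14 members higher, and its largest differences were in Vegfa, an angiogenic growth factor (10.1-fold higher), the transglutaminase Tgm2 (3.36-fold), Klf4 (2.48-fold) and Arg1 (2.08-fold). Heat shock genes had a median of 0.10 with 8 of 13 members higher, and only Hspa1a (5.14-fold) exceeded 2-fold, ahead of Hsph1 (1.96-fold), Hspb1 (1.67-fold) and Hsp90aa1 (1.41-fold). Cytosolic ribosomal protein genes had a median of 0.04 with 14 of 24 members higher, and Rpl8, the largest, was 1.14-fold higher. Rpl14 was 1.12-fold, Rps9 1.11-fold and Rps6 1.08-fold higher. Type I interferon response genes had a median of -0.14 with 10 of 15 members lower, by 1.69-fold for Stat2, 1.59-fold for Ddx58, 1.50-fold for Cmpk2 (below the floor on both arrays) and 1.45-fold for Oasl2. The only member at least 2-fold apart, Cxcl10, was higher (log2 values of 5.36 with PBS and 6.41 with intralipid). Cell cycle genes had a median of -0.07 with 11 of 19 members lower, led by Rrm1 (1.73-fold lower) and Pcna (1.51-fold), with Mcm3 (1.30-fold) and Mcm6 (1.27-fold) behind. Markers of resident peritoneal macrophages stood apart as higher, with a median of 0.19 over 6 members, 5 higher and 1 lower (Prg4 1.24-fold, Tgfb2 1.17-fold, F10 1.16-fold, Gata6 1.12-fold). Marker lists were not run under the alternative settings.

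Genes of lipid handling did not move together. Lipid droplet genes had a median of 0.00 and a mean of 0.47, with 8 of 17 members higher, 8 lower and 3 at least 2-fold higher. Their median did not stand apart in the main analysis. The list stood apart as higher with its mean and with the higher floor. Plin2, the coat protein of lipid droplets, was 1.65-fold higher. Fatty acid oxidation and PPAR targets had a median of 0.00 with 9 of 21 members higher and 7 lower, and Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid entry, was 1.07-fold higher. Pdk4, another PPAR target, stayed below the floor on all 3 arrays (log2 values of 3.92 with PBS, 4.20 with intralipid and 4.20 with ANGPTL4). Lipolysis and fatty acid uptake genes had a median of -0.03, with Lpl, the lipase itself, 1.20-fold lower and the fatty acid transporter Cd36 1.07-fold higher. The medians were 0.00 for LXR targets, 0.00 for eicosanoid synthesis, 0.00 for lysosome and phagocytosis genes, -0.01 for glycolysis and hypoxia genes, -0.06 for the respiratory chain and -0.08 for NRF2 targets, none of which stood apart in the main analysis. The median and mean differed in sign for glycolysis and hypoxia genes (mean 0.15).

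At a threshold of 1.5-fold, the counts were 509 higher and 560 lower, so the excess of higher genes held for large differences only. The interferon, cell cycle, ribosomal, alternative activation and heat shock lists lost their call under at least 1 alternative setting, and the other 5 lists kept it under all that were run.

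**Figure D1:**
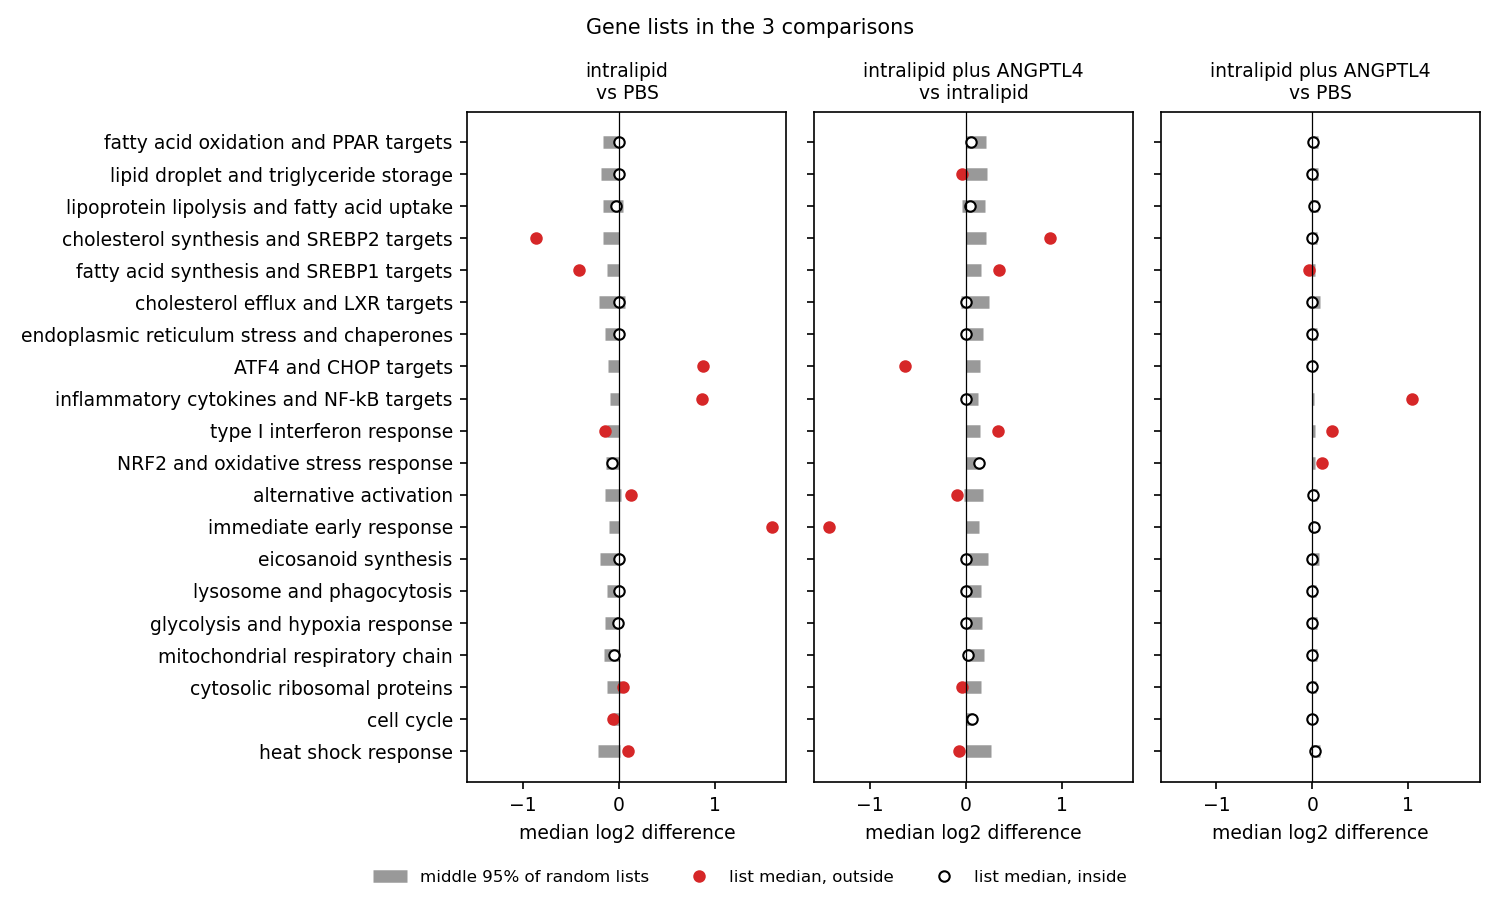
Median log2 difference (x axis) of each of the 20 gene lists (rows) in each of the 3 comparisons (panels), with 1 array per group. Filled points lie outside and open points inside the middle 95% of the medians of 10000 random lists, drawn as grey bars; immediate early genes reach 1.59 in the left panel and -1.43 in the middle one, and inflammatory genes 1.04 in the right one.

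Whether ANGPTL4 altered the cells' state under the lipid load was read from the array with intralipid plus ANGPTL4 against that with intralipid alone. The protocol does not say whether the other cultures had a mock pre-incubation or whether the protein was checked for endotoxin, so these arrays may differ by more than ANGPTL4. Many of the genes above differed again, in the opposite direction. Fosb was 20.8-fold lower with ANGPTL4, Lsmem1 20.6-fold, Cytip, a regulator of lymphocyte adhesion, 18.9-fold, Osm 17.1-fold and Inhba 16.0-fold. Kcnj2 was 24.5-fold higher. The gene with the largest difference, however, was Gpr84 (probe set 10433101), a receptor for medium-chain fatty acids, which was 52.7-fold higher with ANGPTL4, and Acod1, the enzyme that makes itaconate, was 22.2-fold higher. Among 10064 genes, 255 were at least 2-fold higher and 231 at least 2-fold lower with ANGPTL4 than with intralipid alone.

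The list of large differences upward continued with Tlr1 (9.94-fold), Tgfbi (7.37-fold), Clec5a (7.21-fold), Marcksl1 (7.19-fold), Rassf4 (6.61-fold), the adhesion molecule Icam1 (6.32-fold) and AW112010 (6.08-fold). Downward it continued with Dusp10 (14.6-fold), Il6 (13.1-fold), Vegfa (11.6-fold), Tnfaip6 (10.4-fold) and the phosphodiesterase Pde7b (9.98-fold). Kcnj2 and AW112010 lay below the floor on the intralipid array, and Fosb, Lsmem1, Il6 and Tnfaip6 with ANGPTL4, so these folds and ranks depend on values near background too. Against the floor itself they would be 12.2-fold for Kcnj2, 4.63-fold for AW112010, 16.7-fold for Fosb, 12.4-fold for Lsmem1, 2.41-fold for Il6 and 7.38-fold for Tnfaip6. Of the 255 higher genes, 94 were at least 2-fold lower with intralipid than with PBS, 55 were at least 2-fold above PBS with ANGPTL4, and 113 were neither. The groups of 94 and 55 overlap, with Tlr1 for example in both.

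Of the 20 lists, 3 stood apart as higher with ANGPTL4 than with intralipid alone and 6 as lower. Cholesterol synthesis genes had a median of 0.88 with 19 of 21 members higher, among them Hmgcs1 (5.60-fold), Idi1 (4.49-fold), Cyp51 (3.87-fold) and Stard4 (3.80-fold). Fatty acid synthesis genes had a median of 0.35 with 13 of 18 members higher, among them Mid1ip1 (1.95-fold), Elovl6 (1.90-fold, or 1.39-fold against the floor), Scd2 (1.82-fold) and Gpam (1.66-fold). Type I interferon response genes had a median of 0.34 with 9 of 15 members higher, among them Ifih1 (2.39-fold), Ddx58 (2.10-fold), Stat2 (1.83-fold) and Ifit1 (3.91-fold, or 1.91-fold against the floor). Elovl6 and Ifit1 lay below the floor with intralipid alone. Immediate early genes had a median of -1.43 with 25 of 27 members lower, among them Rgs1 (9.64-fold), Dusp1 (9.42-fold) and Nr4a1 (8.45-fold). ATF4 and CHOP targets had a median of -0.63 with 21 of 25 members lower, led by Trib3 (7.10-fold), Ddit3 (6.34-fold), Sesn2 (4.86-fold) and Ddit4 (4.48-fold).

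The alternative activation list had a median of -0.09 with 8 of 14 members lower (after Vegfa, Klf4 3.02-fold, Tgm2 2.47-fold and the mannose receptor Mrc1 1.49-fold). The heat shock list had a median of -0.07 (Hspa1a 6.18-fold, Hsph1 1.80-fold, Hspb1 1.41-fold and Bag3 1.38-fold lower), and ribosomal protein genes had one of -0.04 with 15 of 24 members lower (Rpl14 1.12-fold, Rps19 1.11-fold, Rps9 1.11-fold, Rpl6 1.06-fold). Lipid droplet genes had a median of -0.04 and stood apart as lower, with 9 of 17 members lower. Hilpda was 8.05-fold lower, the triglyceride synthesis enzymes Gpat3 and Dgat1 3.44-fold and 3.21-fold, and the lipase Pnpla2 1.34-fold. Plin2 was 1.24-fold lower with ANGPTL4, Lpl 1.24-fold higher, Cpt1a 1.44-fold higher and Cd36 1.02-fold lower. On the log2 scale these were -0.31, 0.31, 0.53 and -0.03. The robust SD of genes of like expression was 0.25 for Plin2, Lpl and Cd36 and 0.31 for Cpt1a.

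Inflammatory cytokines and NF-kB targets split. Their median was 0.00, inside the middle 95% of random lists, with 7 members at least 2-fold higher with ANGPTL4 than with intralipid alone and 7 at least 2-fold lower. Acod1 and Icam1 were among the former, and Osm and Il6 among the latter. The medians of the other lists were 0.14 for NRF2 targets, 0.07 for cell cycle genes, 0.05 for fatty acid oxidation and PPAR targets, 0.04 for lipolysis and uptake and 0.03 for the respiratory chain. They were 0.00 for LXR targets, chaperones, eicosanoid synthesis, lysosome and phagocytosis genes, and glycolysis and hypoxia genes. Resident peritoneal macrophage markers also had a median of 0.00. None of these stood apart in the main analysis, but NRF2 targets did so as higher under 4 alternative settings and cell cycle genes under 2. The calls for lipid droplet and alternative activation genes ended without the expression floor, that for heat shock genes with the higher floor and that for ribosomal protein genes with the mean of the list.

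**Figure D2:**
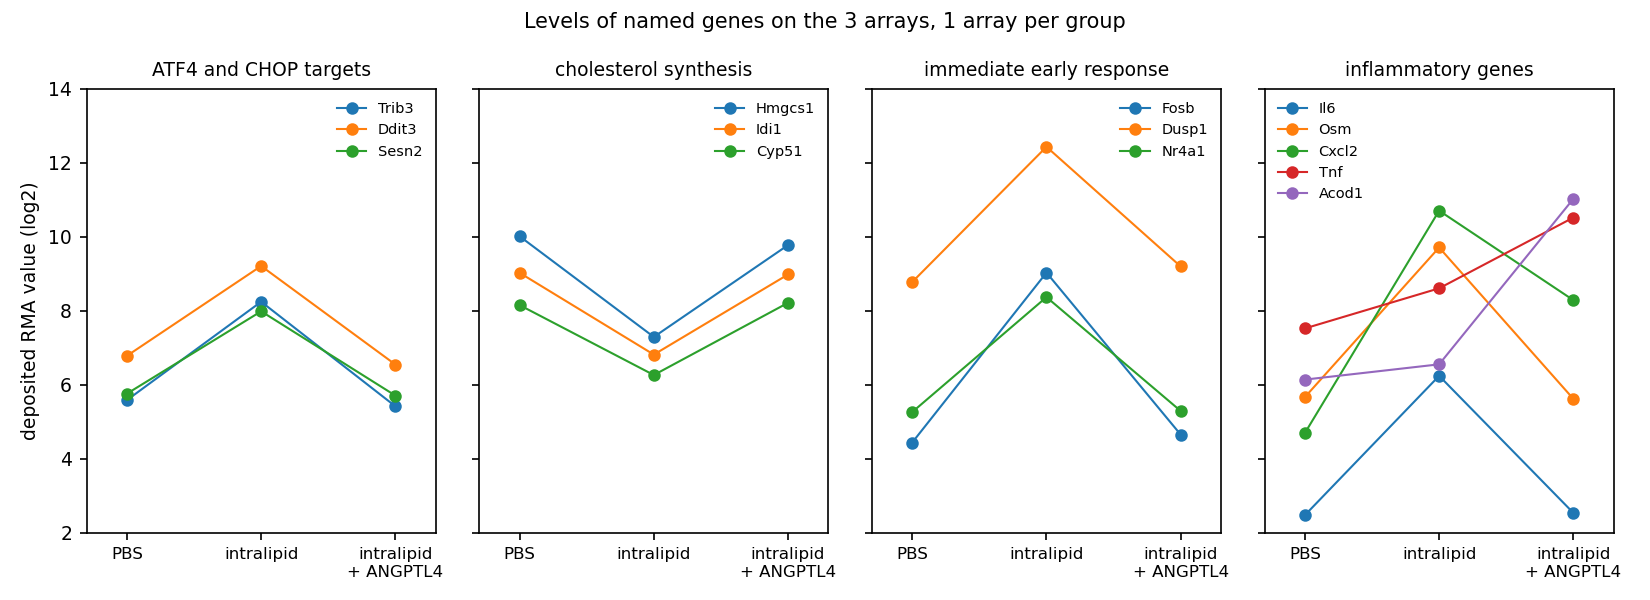
Deposited RMA values on the log2 scale (y axis) of named genes on the PBS, intralipid and intralipid plus ANGPTL4 arrays (x axis), with 1 point per array and lines joining the points of a gene. Stress, sterol synthesis and immediate early genes return near their PBS level with ANGPTL4, as do Il6 (2.48, 6.24 and 2.54) and Osm, while Acod1 (6.14, 6.55 and 11.03) and Tnf are highest with ANGPTL4. Il6 lies below the floor with PBS and with intralipid plus ANGPTL4.

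How much of the intralipid difference was left with ANGPTL4 was measured over the genes at least 2-fold apart between intralipid and PBS. For the 252 higher genes, the median share that remained was 5.57%. With ANGPTL4, 144 of them lay between their PBS and intralipid levels, 100 at or below PBS and 8 at or above intralipid, and 17 were still at least 2-fold above PBS. For the 133 lower genes, the median share was 2.18%, with 71 between both levels, 62 at or above PBS, and 0 still at least 2-fold below it. Noise on the intralipid array makes genes selected on it fall back, which lowers the share, while noise on the PBS array, which both differences use, raises it. With 1 array per group, neither amount could be estimated. Median polish, the usual summary step of RMA, may also lower the share. In simulations of 25 probes on 3 arrays, a true difference of 0.1 came out as a median of 0. Those simulations held a difference on 1 array only and a noise not estimated from these data, so the size of this effect here is not known. With each array centred on its median, the observed shares were 3.21% and 5.97%.

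Of the 252 genes higher with intralipid, 195 were at least 2-fold lower with ANGPTL4, against 5.77 for independent lists of these sizes. In the other direction 95 genes overlapped with the floor reached on any of the 3 arrays, and 94 with the floor applied to each pair of arrays, against 3.36. Independent lists leave out the shared array. Simulated noise alone put 0 genes in either overlap, being too small for 2-fold differences, so it gives no chance value here. Across genes, the difference of intralipid from PBS and that of ANGPTL4 from intralipid had a Pearson's r of -0.87. Their covariance was -0.18. Simulated noise alone gave an r of -0.50 and a covariance of -0.005. The shared array fixes that r when noise is alike on all arrays. That covariance restates the noise put in, which holds no spread between cultures, so neither is a chance value. Part of the overlap may come from the shared array, and with 1 array per group it could not be split.

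**Figure D3:**
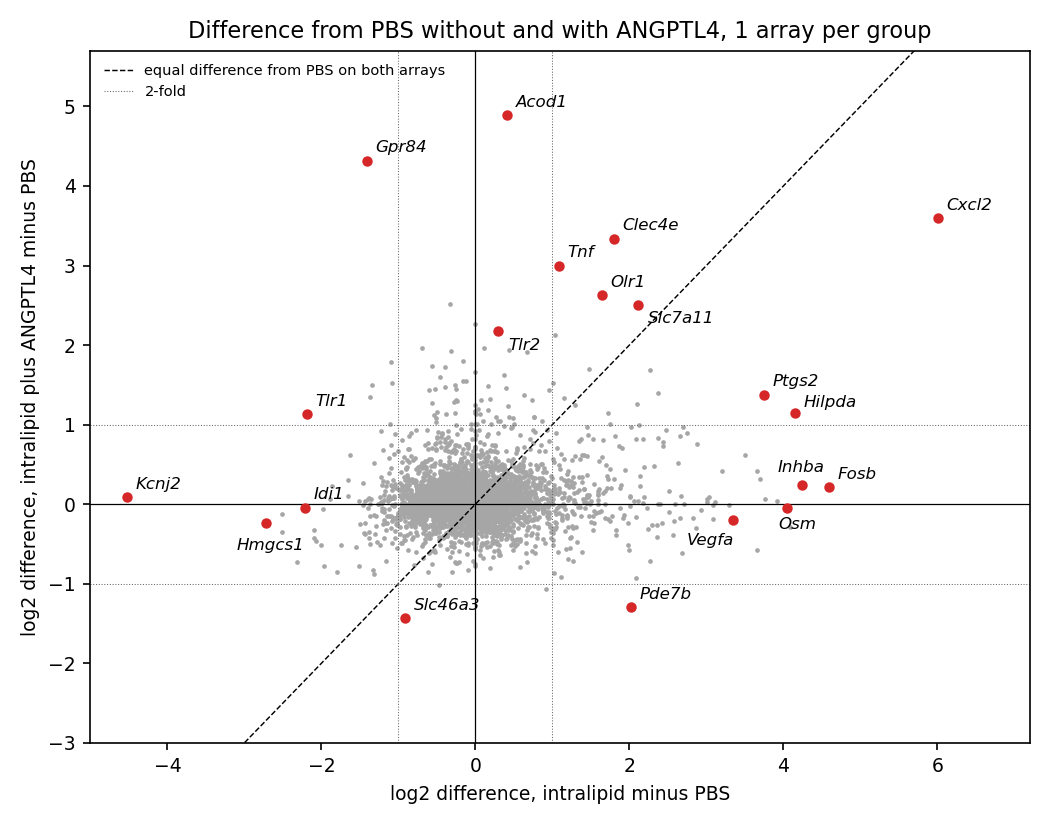
Log2 difference from PBS with intralipid (x axis) against that with intralipid plus ANGPTL4 (y axis), 1 point per gene past the floor, with 1 array per group and named genes in red. The 252 genes at least 2-fold higher and the 133 at least 2-fold lower with intralipid lie right and left of the vertical dotted lines, most of them near 0 on the y axis; Acod1 (4.89) and Gpr84 (4.32) lie highest on it.

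The array with intralipid plus ANGPTL4 against PBS shows what differed when both lipid and inhibitor were present. Among genes with a name the differences were almost all upward, and they were led by inflammatory genes. Acod1 (probe set 10416837) was 29.6-fold higher than with PBS, Gpr84 19.9-fold, Cxcl2 12.1-fold, Clec4e, a receptor for mycobacterial glycolipids, 10.1-fold, and the cytokine Tnf 7.99-fold. Olr1, a scavenger receptor for oxidised lipoprotein, was 6.19-fold higher, Marcksl1 5.74-fold, the cystine transporter Slc7a11 5.69-fold, the NF-kB inhibitor Nfkbie 4.81-fold and Tlr2 4.51-fold. Cxcl2 lay below the floor with PBS, and its difference against the floor would be 9.92-fold. Among 9995 genes, 85 were at least 2-fold higher and 4 at least 2-fold lower.

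The 4 lower genes were Slc46a3 (2.69-fold), Pde7b (2.45-fold), Zdhhc14 (2.10-fold) and the Fc receptor Fcgr1 (2.01-fold). The next were Thbs1 (1.91-fold), Dio2 (1.89-fold), Fgd4 (1.83-fold), Eps8 (1.82-fold), Socs6 (1.81-fold) and St3gal5 (1.81-fold). Of the 85 higher genes, 76 lay above their intralipid level, 55 of them by at least 2-fold, and 9 lay at or below it. Among the 9 were Cxcl2, Ptgs2, Hilpda (2.21-fold above PBS) and Nlrp3. With intralipid alone, 17 of the 85 were also at least 2-fold above PBS, against 2.12 for independent lists, which leave out that both comparisons share the PBS array. With that array shared, Pearson's r across genes between both differences from PBS was 0.12 with a covariance of 0.01. Simulated noise alone gave 0.50 and 0.005. The shared array and the noise put in fix these beforehand, so they give no chance value.

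Of the 20 lists, 3 stood apart as higher than with PBS and 1 as lower. Inflammatory cytokines and NF-kB targets had a median of 1.04, with 26 of 29 members higher, 1 lower and 15 at least 2-fold higher (percentile 100). Icam1 was 3.91-fold higher. Type I interferon response genes had a median of 0.21 with 10 of 15 members higher (Ifit1 2.72-fold, or 1.90-fold against the floor, Ifih1 just under 2-fold, the chemokine Cxcl10 1.85-fold, Gbp3 1.56-fold). Cxcl10 had a log2 value of 6.25 with ANGPTL4, below its 6.41 with intralipid alone. NRF2 and oxidative stress genes had a median of 0.10 with 20 of 26 members higher and 0 of them 2-fold (Abcc1 1.85-fold, the glutathione synthesis subunit Gclm 1.63-fold, Txnrd1 1.60-fold, Cbr3 1.50-fold). Fatty acid synthesis genes had a median of -0.03 with 11 of 18 members lower (Scd2 1.41-fold, Mid1ip1 1.34-fold, Elovl5 1.25-fold, Elovl6 1.12-fold). Resident peritoneal macrophage markers had a median of 0.27 over 6 members, 4 higher and 2 lower, and stood apart as higher (F10 1.68-fold, Cxcl13 1.28-fold, Prg4 1.24-fold, Tgfb2 1.17-fold). Over all 11 measured members, with or without the floor, the median log2 value was 5.07 with PBS and 5.01 with ANGPTL4.

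Unlike the inflammatory list, 3 other lists with large medians for intralipid alone were close to PBS here. Cholesterol synthesis genes had a median of 0.00 with 10 of 21 members higher and 8 lower, ATF4 and CHOP targets one of 0.00 with 12 of 25 higher and 7 lower, and immediate early genes one of 0.01 with 14 of 27 higher and 12 lower. The mean for ATF4 and CHOP targets was 0.18, and 1 member, Slc7a11, exceeded 2-fold. Lipid droplet genes had a median of 0.00, with Plin2 1.33-fold higher. Fatty acid oxidation and PPAR targets had a median of 0.01, with Cpt1a 1.54-fold higher. Lipolysis and uptake genes had a median of 0.02, with Lpl 1.03-fold and Cd36 1.05-fold higher. Medians were 0.02 for heat shock and 0.01 for alternative activation genes. They were 0.00 for LXR targets, chaperones, eicosanoid synthesis, lysosome and phagocytosis, glycolysis and hypoxia, the respiratory chain, ribosomal proteins and the cell cycle. None of these stood apart from random lists in the main analysis.

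At 1.5-fold the counts for this comparison were 237 higher and 53 lower, and at 3-fold 25 and 0. No other alternative moved the counts of this comparison by over 1.5 times.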

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

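Signal in probe sets that carry no gene name or several names was left out of the comparisons above, and counting it was chosen after the data were examined. Of 12146 probe sets with no gene listed, 4095 reached the floor for intralipid against PBS. Of these 4095, 294 were at least 2-fold apart, 209 of them higher and 85 lower. Between intralipid plus ANGPTL4 and intralipid, 360 of 4179 past the floor were so, 198 of them higher and 162 lower. Between intralipid plus ANGPTL4 and PBS, 169 of 4102 were, 132 of them higher and 37 lower. These shares were larger than among genes with 1 symbol, where 385 of 10049, 486 of 10064 and 89 of 9995 were 2-fold apart in the same order. Of 1621 probe sets with several gene symbols, 771 reached the floor for intralipid against PBS, and 51 of these were at least 2-fold apart, 44 of them higher. For intralipid plus ANGPTL4 against intralipid, 53 of 770 past the floor were at least 2-fold apart, 47 of them lower. Against PBS, 3 of 767 were so, with 0 of them lower.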

How the results depend on the processing

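One alternative, leaving out list members identical on all 3 arrays, was chosen after seeing the data. The fold threshold moved the gene counts most, by its own construction. At 1.5-fold, 509 genes were higher and 560 lower for intralipid against PBS, 831 and 498 for ANGPTL4 against intralipid, and 237 and 53 for ANGPTL4 against PBS. At 3-fold these counts were 117 and 20, 59 and 102, and 25 and 0. Under the other 6 alternatives, all 36 counts lay within 1.5 times those reported. The median remaining share was not computed under quantile normalization and stayed below 7% in each alternative run. For higher genes it was 3.21% with arrays centred on their medians. For lower genes it was 0% at 1.5-fold, 6.73% at 3-fold, 6.42% with the floor at the higher percentile and 5.97% with centred arrays. The cause of these shifts was not tested. Of 206 list medians recomputed, 190 stayed apart from random lists and 16 did not. These were in the interferon, cell cycle, ribosomal, alternative activation, heat shock and lipid droplet lists. None of them changed sign. A further 15 medians or means that lay inside the middle 95% in the main analysis stood apart under an alternative. For ANGPTL4 against intralipid these were 4 for NRF2 targets and 2 for cell cycle genes (higher), and 1 each for eicosanoid synthesis, glycolysis and hypoxia, and lysosome genes (lower). For intralipid against PBS they were 2 for lipid droplet genes and 1 each for eicosanoid synthesis and lysosome genes (higher), and for ANGPTL4 against PBS 1 for ATF4 and CHOP targets (higher) and 1 for LXR targets (lower). With the higher floor, the cell cycle list had too few members for a value. Of 644 recomputed values of named genes past the floor, 637 moved by no more than the robust SD of genes of like expression and 7 by more (Mid1ip1 in 3 comparisons, Elovl6, Prg4 and Socs6), with no sign changed. The 24 values of Angptl4 and Pdk4, below the floor, had no such SD and moved by at most 0.04. No paired analysis was possible because each group was 1 array. Signal near the floor limits low genes, and 44.5% of the 20% of genes with the lowest expression past the floor held 1 value on all arrays.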

Other observations

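The gene families in the next 2 paragraphs, and all tests below except those of the endotoxin list and of median polish, were chosen after their values were seen. Histone genes were higher with intralipid. Of 30 genes with numbered histone symbols, 20 passed the floor, and with intralipid 17 were higher than with PBS, 1 lower and 10 at least 2-fold higher, with a median of 1.09. Among those past the floor on both arrays, H4c9 was higher by 3.29 on the log2 scale and H1f2 by 2.68. With ANGPTL4 the median against intralipid was -1.33 and against PBS -0.17, with 14 members below PBS. Cell cycle genes were slightly lower with intralipid than with PBS (median -0.07). Histone genes of 1 class are nearly identical in sequence, so their probe sets are not independent measurements. The direction held with centred arrays, loess and quantile normalization.

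Toll-like receptor genes went the other way. Of 9 past the floor, 7 were lower with intralipid than with PBS, 1 was higher and 1 was identical, with a median of -1.04. Tlr1, Tlr6, Tlr7, Tlr8 and Tlr13 were each at least 2-fold lower, while Tlr2 was higher by 0.29. Against intralipid alone, 8 were higher with ANGPTL4 (median 1.12). Against PBS the median was 0.00, with Tlr1 and Tlr2 at least 2-fold higher. The direction of both nonzero medians held under the same 3 scalings.

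Among genes with 1 symbol, most differences between intralipid and PBS were absent with ANGPTL4. Array noise independent between genes would leave about 5% of the fixed lists apart, but 50% of the 20 stood apart between intralipid and PBS. That share was known when this comparison was set up, and several of these lists lost their call under an alternative setting. It concerns intralipid against PBS only and does not address why differences were absent with ANGPTL4. A disturbance of many genes at once, from handling of the intralipid cultures or their array, stays open because 1 array carried intralipid alone. A candidate biological explanation, that ANGPTL4 stopped the lipid from acting, cannot be told apart from it. PBS and intralipid plus ANGPTL4 differed in 23.1% as many genes with 1 symbol as intralipid and PBS. Of the 10 lists that stood apart with intralipid, 80% no longer did so in the same direction, but both values restate the pattern. Among probe sets with no gene listed, 294 of 4095 past the floor were at least 2-fold apart between intralipid and PBS. The count between intralipid plus ANGPTL4 and PBS was 169 of 4102, a smaller drop than for genes with 1 symbol. No array with the protein but without lipid was analysed here.

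Inflammatory genes were higher with intralipid plus ANGPTL4 than with PBS. An incomplete block of the lipid response would leave genes at or below their intralipid level; of the 85 genes at least 2-fold above PBS, which were picked on the ANGPTL4 array, 89.4% lay above it and 10.6% (9 genes, such as Cxcl2 and Ptgs2) did not. In the fixed inflammatory list, 14 of the 26 members above PBS (53.8%) lay above their intralipid level, 7 of them at least 2-fold, and 12 did not, so an incomplete block stays open for this list. A second stimulus in the cultures given the recombinant protein may account for genes above that level. It could be endotoxin in the preparation or an action of the protein itself. In a list of 34 endotoxin-induced genes, 24 passed the floor. Their median was 0.49 for ANGPTL4 against intralipid (percentile 100, with 16 higher, 6 lower and 2 identical). Against PBS it was 0.78 (22 higher, 1 lower and 1 identical). The list was written down before its own values were seen, but after the inflammatory pattern was. Its rise may therefore restate that pattern and does not decide on this explanation. The endotoxin list also stood apart with intralipid alone (median 0.09). The fixed inflammatory list did not stand apart for ANGPTL4 against intralipid (median 0.00, 14 higher and 13 lower). Acod1 and Tnf were among its 14 members above both their PBS and their intralipid level with ANGPTL4. Il6 and Osm lay near PBS (log2 values of 2.54 against 2.48, and 5.62 against 5.67), with Il6 below the floor on both of these arrays. Contamination was not told from an effect of the protein.

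Many probe sets held 1 identical value on all 3 arrays. A floor or filter on low values would leave high genes untouched, but 10.4% of the 20% of genes with the highest expression past the floor held 1 value. Median polish, the usual summary step of RMA, may account for it: in simulations of noise without any array effect it gave 1 value on all 3 arrays in 77.4% of probe sets of 25 probes and 43.5% of those of 11, and with 4 arrays in 0%. In the same simulations a true difference of 0.3 on the second of 3 arrays came out as a median of 0.15 for 25 probes and one of 1 as 0.87, so small differences in these data may be understated. The noise in these simulations was a set value, not one estimated from the data, so the simulated shares and shrinkage need not hold here. Values in the identical rows also recur: 14722 rows held 2322 distinct values, and 6.64% of the rows held a value found in no other row. The simulated values were continuous and did not model this recurrence, so it did not decide between the explanations.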
